A study of Triticum aestivum with 10 samples.

How the data were processed

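Leaf RNA of 10 wheat samples was hybridised as biotin-labelled cRNA to an Affymetrix wheat array. The authors deposited 1 table of log2 values for 61179 probe sets; the base of 2 was taken from the values, which run from 0.93 to 16.34. Per the submitters' processing notes the tools were GCOS, MAS5, RMA and GCRMA, with no versions, and which of them made the table is not given in the sources used here. These methods differ in how they treat dim probe sets, so changes of transcripts near the floor depend on that step. Scan dates, batches and detection calls were not analysed here, so no comparison within batches was made. Nothing in the labels says that plants were pooled, and p-values measure the spread between these arrays.

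The values were used as deposited, without a further normalization. The 64 reporter probe sets were left out, leaving 61115 wheat probe sets. No Affymetrix control probe sets were in the table, so the planned 3 prime over 5 prime check of RNA quality could not be made. Probe sets above their array median in at least 2 arrays were tested (31892), of which 4891 may cross-hybridise and 4963 match several transcripts by the suffix of their names.

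Groups came from the sample titles. limma 3.58.1 in R 4.3.3 was fitted to all 10 arrays with a mean per group, since groups of 2 and 3 leave few degrees of freedom (6 residual, with a prior of 1.67), followed by empirical Bayes and Benjamini-Hochberg adjustment within each comparison at 0.05. Comparisons were Ggt and earthworms each against control, both against each single treatment and against control, the interaction, and a moderated F test; these comparisons, the test, the filter, 24 gene lists and the alternatives were chosen before the data were examined. The model of inoculation and earthworms as added factors and 10 further lists were chosen later. The replicate numbers did not pair the arrays and no block was used.

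Gene names came from the array's platform annotation. Of the wheat probe sets 1273 have 1 gene symbol, 0 several and 59842 none; 1272 were matched by gene number to the gene table of IWGSC CS RefSeq v2.1, used for names only. Most symbols are locus numbers, so after the data were seen a gene was taken as named if its symbol or a synonym is a word, which left 132 tested probe sets of 77 genes. Of the other 807 probe sets with a locus number, 108 were higher and 190 lower with Ggt. Genes named in the text were drawn by the rules below, and not every gene they picked is named. Per comparison, the rules took up to 12 largest rises and 12 largest falls among called genes whose groups do not overlap. Each gene had 1 probe set. Where fewer than 5 passed, the smallest p values in each direction were taken, as values that did not pass. Also taken were the up to 4 smallest p values of each list, and up to 2 rises and 2 falls without a gene name. The latter are given only for the earthworm comparisons and the interaction.

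Gene lists were tested with camera at a preset correlation of 0.01 for lists with at least 5 tested probe sets, with an estimated correlation and fry alongside. Their p-values were adjusted over the lists tested within a comparison, with the fixed and the later lists apart. Only 1 fixed list was tested, so every adjusted p of the redox list from these tests equals its unadjusted p. Of 24 lists fixed as name patterns, 17 had no tested probe set and 1 (redox enzymes) had enough. The others with members were pathogenesis-related, antimicrobial, cold and dehydration, heat shock, photosynthesis and ribosomal. The patterns were planned for gene symbols, titles and descriptions but were matched to symbols and synonyms only. An empty list therefore does not mean that its genes were not measured. The histone, cyclin and tubulin pattern matched 0 probe sets, while lists by gene number held 15 tested histone and 9 tested tubulin probe sets. A further 10 lists were made by gene number after the names and array correlations had been seen and before any test: defence, photosynthesis, tubulin, histone, dehydration, fructan and starch, gibberellin 20-oxidase, translation, glutathione-related and grain tissue; 7 had enough probe sets.

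The fit was tested on simulated data with 200 of 31892 probe sets changed. For Ggt against control it recovered 44% of changes of log2 1 and 86% of log2 3, for earthworms against control 28% and 79%, for both against Ggt 42% and 94%, and for the interaction 17% and 73%. The simulated noise was independent between probe sets, and the number changed was set in advance. These shares therefore do not give the recovery in the real comparisons. Alternatives tried were no filter, a filter at the 75th percentile, a common median, quantile normalization, a pseudocount of 16, a trended robust prior, array weights, only the groups compared, the replicate block, other thresholds (unadjusted p under 0.01 with 2-fold, adjusted p with 2-fold), and each array left out in turn.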

Results

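Leaf transcripts were measured on 10 arrays from wheat (Triticum aestivum) grown for 52 days in sandy soil in a greenhouse. The plants were left alone (control, n = 2), grown with earthworms (n = 2), inoculated with Gaeumannomyces graminis var. tritici (Ggt, the soil fungus that causes take-all, a root disease; n = 3) or given both (n = 3). Earthworms were added 2 weeks after the fungus. The labels call the arrays biological replicates, with 2 to 3 plants per treatment in one field and 3 in another. The questions set by the design were what the fungus changed in the leaf, what earthworms changed, and whether earthworms changed the leaf of an inoculated plant. Values are log2 signals, with lower quartiles of the arrays from 2.37 to 2.43 and upper quartiles from 8.11 to 8.25, and a change of 1 is a doubling. The number of arrays limits the precision, since the controls rest on 2.

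Inoculation set the arrays apart along the first principal component, which held 63.6% of the variance. All 4 uninoculated arrays lay between −160.5 and −75.9 on it, and all 6 inoculated arrays between 48.5 and 97.8. Correlations between arrays across all wheat probe sets were 0.981 to 0.994 within a group and 0.951 to 0.982 between inoculated and uninoculated plants. Control replicate 1 lay at the far end of this component. Ggt replicate 3 stood apart on the second component, at 106.6. The median histone value was highest on Ggt replicates 1 and 2 (7.15 and 7.86), while Ggt replicate 3 (4.98) lay near control (4.86 and 4.77) and earthworms replicate 2 (4.64). It was 5.84 on earthworms replicate 1 and 5.90, 6.09 and 6.46 on the earthworms + Ggt arrays.

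**Figure D1:**
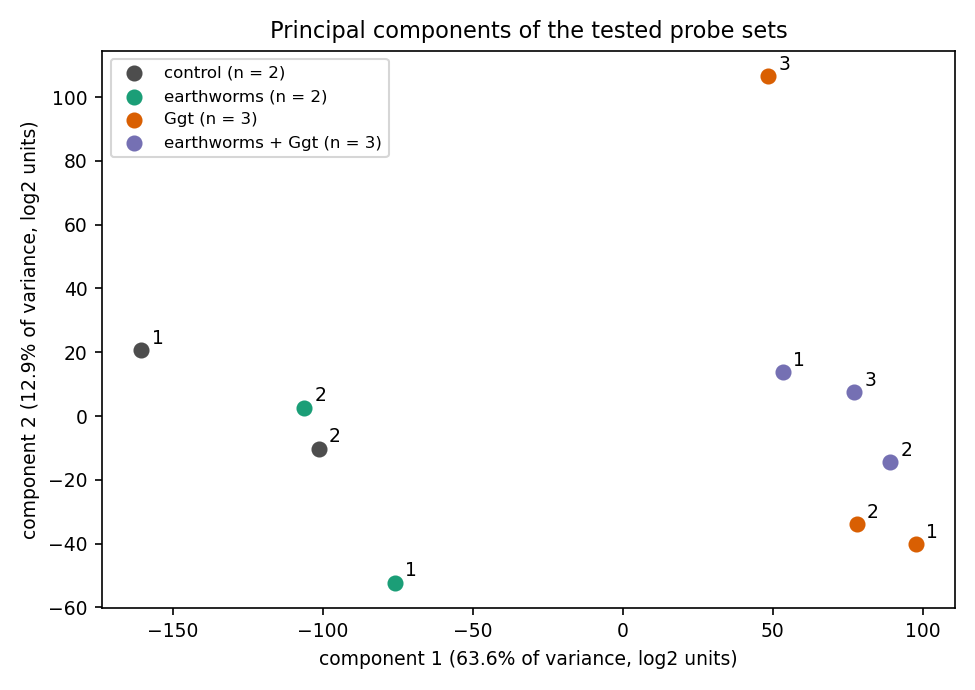
Scores of the 10 arrays on principal components 1 and 2 (log2 units) of the 31892 tested probe sets, coloured by group and numbered by replicate. Inoculated arrays lie at 48.5 or higher on component 1 and uninoculated arrays at −75.9 or lower.

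In leaves of Ggt plants compared with control, transcripts of 2 late-embryogenesis and abscisic-acid-associated genes fell. Rab15, a dehydrin-type gene, averaged 14.04 ± 0.33 (SD, n = 2) in control and 6.23 ± 0.23 (SD, n = 3) with Ggt on probe set Ta.2704.1.S1_at, a log2 change of −7.81 (SE 0.37, limma adjusted p = 4.87e-05), and changed by −6.81 on Ta.2704.1.S1_x_at. On TaAffx.46097.2.S1_at it went from 11.82 ± 0.64 (SD, n = 2) to 2.26 ± 0.02 (SD, n = 3), below the lower quartile of the arrays, so the change of −9.57 (adjusted p = 4.34e-06) is one to the floor and not an exact size. LEA1, a late embryogenesis abundant protein gene, changed by −9.36 (SE 1.67, adjusted p = 0.00571), to a mean of 4.10 with 1 of the 3 arrays at 3.42, near the array medians, so its size is not exact. XIP-I, an inhibitor of fungal xylanases, changed by −4.25 (SE 0.47, adjusted p = 0.00117). Raftin1b, a relative of an anther protein, rose by 4.31 (SE 0.42, adjusted p = 0.000806) from a control mean of 3.25 (arrays at 2.56 and 3.95), near the floor, so its size is not exact, and the beta-tubulin tubb1 rose by 1.98 (SE 0.23, adjusted p = 0.00148).

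Other named genes that fell included PIMT, which repairs damaged proteins (−2.35), the fructan exohydrolase 6-FEH (−2.11), the zeta glutathione transferase GSTZ1 (−1.25), the calcium channel TPC1 (−1.15), the cap-binding factor eIF4E (−0.99) and DMAS1, an enzyme of iron-chelator synthesis (−0.88). The fall of DMAS1 is on 1 of its 3 probe sets, the others being at 0.02 and −0.07. Named genes that rose included glyoxalase I (2.07), the ribosomal protein RPL9 (2.06) and the gibberellin 20-oxidase GA20ox1A (1.78). Glyoxalase I was at 10.93 and 12.12 in control and 13.22 to 13.87 with Ggt. It was already at 13.38 and 13.53 with earthworms alone, and the fungus gave no call for it in plants with earthworms. TaGlu1a, a beta-glucosidase that acts on stored defence glucosides, rose by 4.93 (adjusted p = 0.00888), a call that ended without control replicate 1 (adjusted p = 0.07). In all, 3989 probe sets were higher and 5741 lower at an adjusted p of 0.05 among 31892 tested. Of 132 named probe sets, 20 were higher, 21 lower and 91 did not pass.

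By group, all 4 measured probe sets of the dehydration list (Rab15 and LEA1) fell. The redox enzyme list, fixed before the data were examined, held 5 tested probe sets of 2 genes, GSTZ1 and the peroxidase PER1, of which 0 rose, 4 fell and 1 did not pass; adjusted over the list alone, 5 fell. Without control replicate 1, 2 of the 3 GSTZ1 probe sets (adjusted p = 0.0900 and 0.143) and PER1 (−2.88, to 2.15, near the floor; 0.289) no longer passed, nor did the same GSTZ1 probe sets without control replicate 2 (0.127 and 0.0757), or PER1 without any one inoculated array (0.0659 to 0.0930). The camera adjusted p of the redox list was 0.0072, and adjusted p = 0.0598 with an estimated correlation. As the only fixed list tested, it had no other list to be adjusted with, so these equal unadjusted values here and in the other comparisons. Lipid transfer protein LTP3 fell on 1 of 2 probe sets (−0.92; adjusted p = 0.0865 without control replicate 1 and 0.0670 without control replicate 2). Single tested members of the heat shock and pathogenesis lists, hsp16.9A (−1.87, SE 2.34) and PR5 (−0.13, SE 1.26), did not pass. The fixed photosynthesis list had 1 of 3 probe sets higher, from PsbP of photosystem II (1.04; 0.40 with adjusted p = 0.112 without control replicate 1). That call passed only with control replicate 2 left out, with adjusted p from 0.0623 to 0.0953 without any one earthworm or inoculated array. The ribosomal list had 2 of 3 higher, RPL9 and 1 probe set of RPS29 (1.42; adjusted p = 0.0529 without control replicate 1), while the other RPS29 probe set was at −0.51 and lower when adjusted over the list alone (2 higher, 1 lower).

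The lists made from gene names after the data were seen gave 4 higher, 4 lower and 5 not passing of 13 defence probe sets, with XIP-I lower and peroxidase Prx1 higher on 3 of 4 probe sets (up to 0.93); without control replicate 1 the list had 1 higher and 2 lower. Of 22 photosynthesis probe sets 4 rose, of 9 tubulins 2 rose, and of 15 histones 2 rose, both of wcH2B-8 (1.70 and 1.23). All 4 photosynthesis calls ended without control replicate 1, of PsbP (adjusted p = 0.112), rbcl (0.139), FBP (0.0607) and Trx-M (0.0505), as did the tubb3 call (0.192). There were 7 photosynthesis calls without control replicate 2 and 2 without Ggt replicate 2. The tubb3 call also ended without Ggt replicate 1 or 2 (0.0750 and 0.0710). Without Ggt replicate 3, 6 tubulins and 11 histones were called. The 2 histone calls ended without control replicate 1 (adjusted p = 0.0755 and 0.0761) and without control replicate 2 (0.0593 and 0.0898), the second also without Ggt replicate 1 or 2 (0.0606 and 0.0526). Camera called the photosynthesis, tubulin and histone lists higher (adjusted p = 0.0256, 0.0162 and 0.0117), and each had adjusted p = 0.707 with an estimated correlation. Without control replicate 1 the photosynthesis and tubulin calls ended (adjusted p = 0.237 and 0.130), and without Ggt replicate 3 the photosynthesis call did (0.200). Of 3 gibberellin 20-oxidases 2 rose, GA20ox1A and GA20ox1B (1.45). GA20ox1B passed with 4 of the 10 arrays left out in turn (adjusted p = 0.178 and 0.123 without control replicate 1 and 2, 0.103, 0.0553 and 0.0516 without Ggt replicate 1, 2 and 3, and 0.0696 without earthworms + Ggt replicate 2), and not without the filter (0.108).

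Without control replicate 1 the count of Ggt against control fell to 4711 (1915 higher and 2796 lower), of which 4473 were among the 9730; 9 of the 24 genes named by rule then no longer passed. Rab15, LEA1, XIP-I, raftin1b, tubb1, PIMT, 6-FEH, GSTZ1, TPC1, eIF4E, DMAS1, glyoxalase I, RPL9 and GA20ox1A passed, on the probe set chosen by the rule, with each of the 10 arrays left out in turn.

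**Figure D2:**
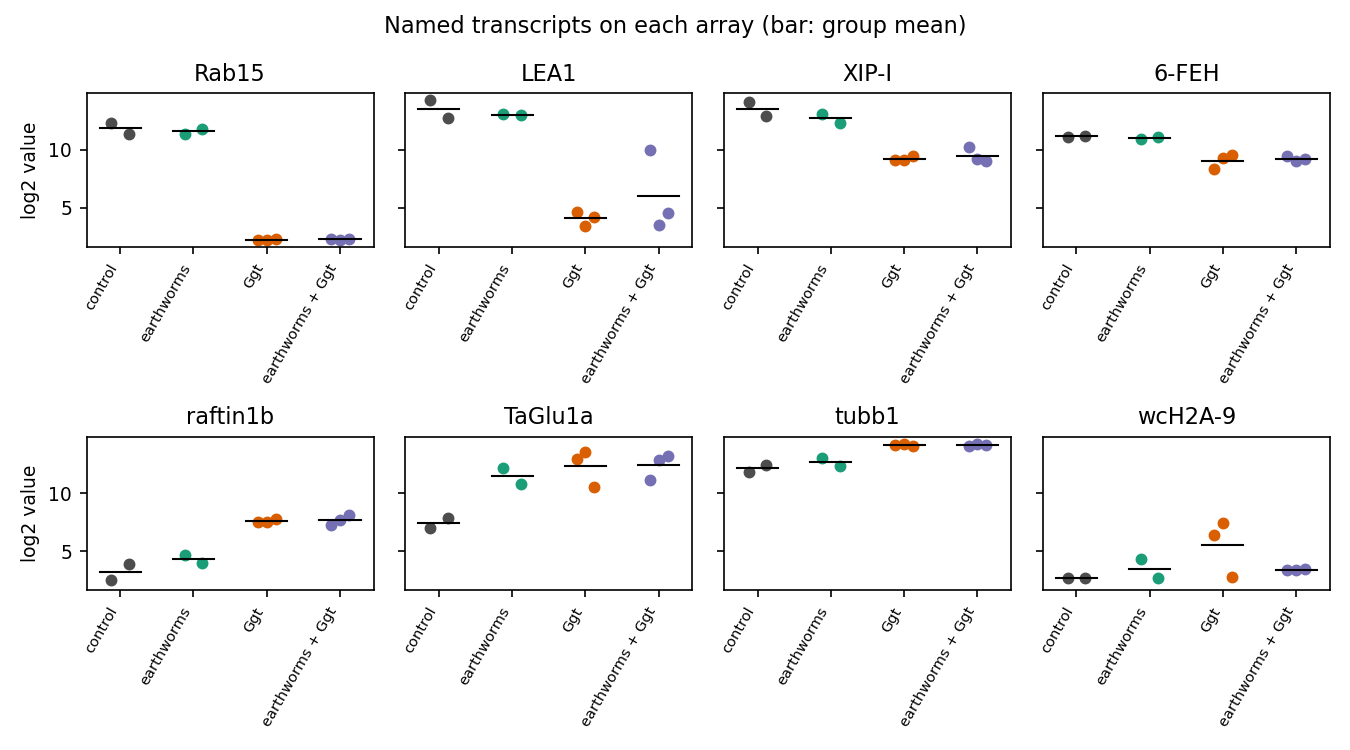
Log2 values (vertical axis) of 8 named transcripts on each of the 10 arrays, by group, with a bar at the group mean. Rab15 on TaAffx.46097.2.S1_at lies near 2.3 on all 6 inoculated arrays, LEA1 is at 9.93 on earthworms + Ggt replicate 1, and wcH2A-9 is high on 2 of the 3 Ggt arrays.

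The fungus was also compared in plants that all had earthworms, using no control or Ggt array in the group means. Rab15 changed by −7.04 on probe set Ta.2704.1.S1_at (SE 0.37, adjusted p = 0.000114) and by −6.16 and −9.27 on the others, the last to the floor, XIP-I by −3.22, PIMT by −2.24 and TPC1 by −1.23, while raftin1b rose by 3.33 and GA20ox1A by 2.22; these 6 genes passed, on the probe set chosen by the rule, with each array left out in turn, and the other XIP-I probe set did not without earthworms replicate 1 (0.0555). LEA1 changed by −6.99 (SE 1.67, adjusted p = 0.0279), with earthworms + Ggt replicate 1 at 9.93 and the other two at 3.53 and 4.59; it had adjusted p = 0.0719 without the filter on dim probe sets. Its call also ended without earthworms replicate 1 or 2 (adjusted p = 0.109 and 0.126) and without earthworms + Ggt replicate 2 or 3 (0.0754 and 0.0872). Tubb1 rose by 1.43 and tubb3 by 1.22, calls that both ended without earthworms replicate 2 (adjusted p = 0.0504 and 0.255); tubb3 passed with 3 of the 10 arrays left out in turn. In all 1948 probe sets were higher and 3663 lower, and of 132 named probe sets 7 were higher, 17 lower and 108 not passing.

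The dehydration list fell on 4 of 4 probe sets again, and the redox enzyme list had 2 of 5 lower, both of GSTZ1 (camera adjusted p = 0.0202; adjusted p = 0.0922 with an estimated correlation). Both ended without earthworms replicate 2 (adjusted p = 0.0582 and 0.156), and the second also without either control array (0.0525), earthworms replicate 1 (0.150) or any one earthworms + Ggt array (0.0562, 0.110 and 0.118). Tubulins had 2 of 9 higher and photosynthesis 1 of 22 (camera adjusted p = 0.00195 and 0.0271; adjusted p = 0.868 and 0.896 with an estimated correlation); both camera calls ended without earthworms replicate 2 (adjusted p = 0.0696), photosynthesis also without earthworms + Ggt replicate 3 (0.118), and the redox camera call without earthworms replicate 1 (0.095). The 1 photosynthesis probe set called, of rbcl, passed with 2 of the 10 arrays left out in turn (adjusted p = 0.0566 to 0.218 for the others). That rbcl probe set, TaAffx.128414.196.S1_at, was not the one called in Ggt against control, TaAffx.128414.72.S1_at, which did not pass here. Across probe sets the log2 changes of the fungus with and without earthworms, which share no array, correlated at Pearson's r = 0.888 and Spearman's rho = 0.822. This is a description over probe sets, which are not independent replicates. Called in both were 1715 higher and 3045 lower probe sets, against 243.7 and 659.4 for independent lists, and 3 were called in opposite directions. Both comparisons take each probe set's spread from all arrays, so independent lists are not an exact baseline. The count of 5611 fell to 2248 without earthworms replicate 1, 1724 without earthworms replicate 2, 2347 without earthworms + Ggt replicate 2 and 2848 without earthworms + Ggt replicate 3. The replicate number as a block gave 3513.

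**Figure D3:**
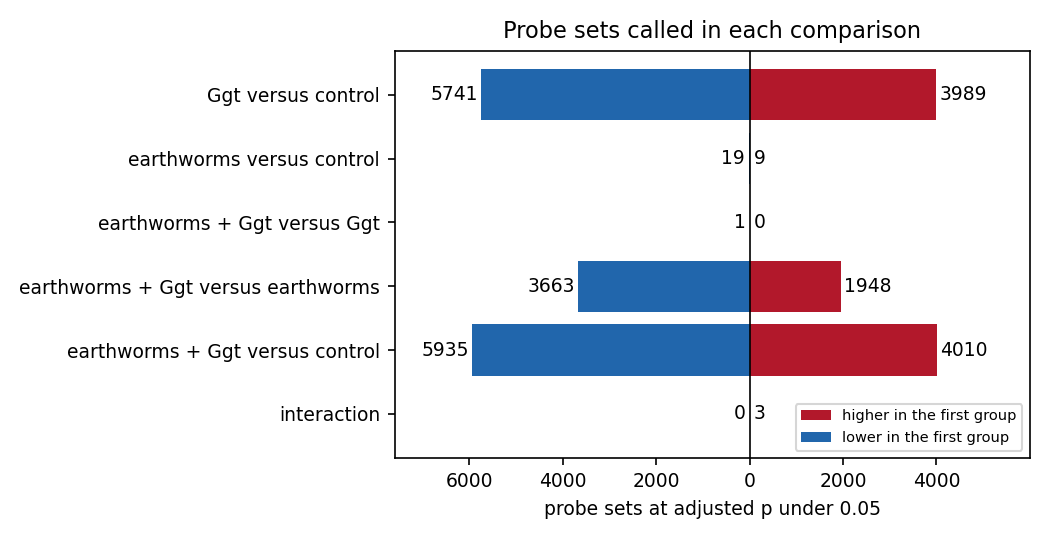
Probe sets with limma adjusted p under 0.05 in each comparison (horizontal axis, number of probe sets), higher to the right and lower to the left. Bars for comparisons of inoculated with uninoculated plants reach 5935, and those for earthworms alone hold 28 and 1 calls.

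Plants with both treatments were also compared with control. Rab15 changed by −7.14 on Ta.2704.1.S1_at, LEA1 by −7.44 and XIP-I by −4.01, while TaGlu1a rose by 4.96 and raftin1b by 4.44, the latter from the same control values near the floor. In all 4010 probe sets were higher and 5935 lower; of 132 named probe sets 22 were higher, 21 lower and 89 not passing. The redox list had 2 of 5 lower (camera adjusted p = 0.0322; adjusted p = 0.114 with an estimated correlation), photosynthesis 5 of 22 higher and tubulins 3 of 9 higher (camera adjusted p = 0.00349 and 0.00415; both adjusted p = 0.703 with an estimated correlation). The redox list had 1 lower without control replicate 1, photosynthesis 3 higher and tubulins 1 higher (tubb1), since tubb3 (adjusted p = 0.162) and Tubb4 (0.92 to 0.47, 0.306) no longer passed. Tubb4 passed with 1 of the 10 arrays left out in turn, and tubb3 ended also without earthworms + Ggt replicate 2 or 3 (0.0701 and 0.0584). Photosynthesis had 3, 2 and 3 higher without earthworms + Ggt replicate 1, 2 and 3, and redox 1 lower without each of them or Ggt replicate 2. The redox camera call ended without control replicate 2 (adjusted p = 0.102). The count of 9945 fell to 4651 without control replicate 1 and 6576 without earthworms + Ggt replicate 2. LEA1 and TaGlu1a then no longer passed without control replicate 1 (adjusted p = 0.0946 and 0.0677).

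Earthworms alone against control changed 28 probe sets, 9 higher and 19 lower, and none of them has a gene name or locus number here. Of the 31892 tested probe sets only 939 have either, so this absence says little about the 28. The largest measured fall was Ta.15129.1.S1_at (−5.03, SE 0.54, adjusted p = 0.0376), to 3.69 ± 1.27 (SD, n = 2), near the floor, so its size and rank are not exact, and the largest rise TaAffx.121392.1.S1_at (3.02, SE 0.35, adjusted p = 0.0471). Of the 132 named probe sets 0 passed (limma); the smallest-p values, which did not pass, were glyoxalase I at 1.93 (adjusted p = 0.204), TaGlu1a at 4.06 (0.335), Prx1 at 0.76 (0.266), the fructan exohydrolase 1-FEH at −0.58 (0.445) and eIF4E at −0.38 (0.456). Over all probe sets 3039 had an unadjusted p under 0.05. The redox list had 0 of 5 called (camera adjusted p = 0.922), and of the lists made later 0 passed. Without control replicate 2, 3 defence, 4 photosynthesis and 2 glutathione-related probe sets were called higher.

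The 28 calls rest on few arrays. They numbered 25 without control replicate 1, of which 8 were shared, 1784 without control replicate 2, 10, 6 and 14 without Ggt replicate 1, 2 and 3, and 6, 7 and 7 without earthworms + Ggt replicate 1, 2 and 3, arrays that enter only through the pooled spread; the replicate block gave 1. The fall of Ta.15129.1.S1_at and the rise of TaAffx.121392.1.S1_at did not pass without control replicate 1 (adjusted p = 0.116 and 0.145). Fitted on the 4 arrays of these groups alone, 0 were called. Of the 28, 5 of 9 higher and 19 of 19 lower were also called in the same direction with Ggt, and 2 of the 9 higher were called lower with Ggt. Both comparisons share the 2 control arrays, and most of the 19 falls ended below the array medians in both.

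In inoculated plants, earthworms changed 1 probe set, Ta.16566.1.S1_at, which averaged 5.03 ± 0.10 (SD, n = 3) with Ggt and 3.35 ± 0.06 (SD, n = 3) with both, a log2 change of −1.68 (SE 0.10, limma adjusted p = 0.0104). Its means in control (3.33), with earthworms (3.29) and with both lie near the array medians, so the fall is to a level near the floor and its size is not exact. Unadjusted, 389 probe sets had p under 0.05. Of the 132 named probe sets 0 passed. Values that did not pass included the histone genes wcH2A-9 (−2.09, SE 1.07), wcH2B-8 (−1.51, SE 0.61) and wcH2A-2 (−1.12, SE 0.41), and the lipid transfer protein LTP3 (0.42, SE 0.20). Rab15 (0.66, SE 0.33, on probe set Ta.2704.1.S1_at, and 0.02 on TaAffx.46097.2.S1_at) and PER1 (0.50, SE 0.27, on Ta.24688.2.S1_a_at) did not pass either. Each of these had an adjusted p of 1. The PER1 probe set that fell with Ggt, Ta.14503.1.S1_at, stayed near the floor. Its arrays lay at 2.14 to 2.17 with Ggt and 2.10 to 2.13 with both. The values with both of wcH2A-9 (3.42) and wcH2B-8 (3.03) lie near the array medians, so these sizes are not exact. The call of Ta.16566.1.S1_at was lost without each of the 2 controls, without Ggt replicates 1 and 2 and without each of the 3 arrays of plants with both, where the count was 0, and without Ggt replicate 3 the count was 4.

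As groups, 0 of 15 histone probe sets passed singly, while camera put the list lower (adjusted p = 1.19e-06; adjusted p = 0.355 with an estimated correlation, 0.347 with 1 probe set per gene and 0.616 with fry). The direction rests on Ggt replicates 1 and 2, since the median histone value of Ggt replicate 3 (4.98) lay below all 3 earthworms + Ggt arrays (5.90 to 6.46). The defence list was higher (13 probe sets, median 0.20; adjusted p = 8.58e-05 and adjusted p = 0.0298 with an estimated correlation), as was the redox list (5 probe sets, adjusted p = 0.00326 and adjusted p = 0.0444). The redox call ended without Ggt replicate 1, Ggt replicate 3 or earthworms + Ggt replicate 1 (adjusted p = 0.0987, 0.0936 and 0.0678), and fry, which asks whether members move one way on balance, gave 0.134 for redox and 0.0742 for defence. Photosynthesis (adjusted p = 0.0013) and glutathione-related genes (adjusted p = 0.0184) were called higher by camera and had adjusted p = 0.377 and 0.355 with an estimated correlation. Later lists were not kept apart from the fixed ones and can share probe sets with them. The redox and glutathione-related calls therefore need not be separate results. The photosynthesis call ended without Ggt replicate 2 or earthworms + Ggt replicate 3 (adjusted p = 0.489 and 0.243), and the glutathione call without Ggt replicate 1, Ggt replicate 3 or earthworms + Ggt replicate 1 (0.0673, 0.429 and 0.329).

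Whether earthworms acted differently with and without the fungus was tested as an interaction. It passed for 3 probe sets without gene names, Ta.15208.1.S1_x_at (3.80), Ta.30790.3.S1_x_at (2.53) and Ta.16315.2.A1_x_at (2.00), each higher in the 2 controls than in the other 3 groups, and 1752 had an unadjusted p under 0.05. Their means with earthworms (2.29, 2.54 and 2.79), with Ggt (2.02, 2.29 and 2.65) and with both (2.01, 2.34 and 2.64) lay below the array medians, near the floor, so the falls with earthworms are not exact sizes and little further fall could be measured in inoculated plants. The interaction of each is then close to its fall in uninoculated plants with the sign reversed, and does not show that earthworms acted differently with the fungus. Named genes did not pass; the smallest adjusted p was 0.797, for the Rubisco gene rbcl (1.56), whose probe sets differed in sign, and wcH2A-9 and other histones gave a list shift of adjusted p = 0.0201 (adjusted p = 0.958 with an estimated correlation). That shift ended without control replicate 2 (0.207), earthworms replicate 1 (0.176), Ggt replicate 1 (0.159), Ggt replicate 2 (0.156) or earthworms + Ggt replicate 1 (0.121). The count was 5 without control replicate 1, 762 without control replicate 2, 14 and 12 without earthworms replicate 1 and 2, 7 without Ggt replicate 3 and 1 without any other inoculated array. A moderated F test for any difference from control called 8516 probe sets, and 5559 without control replicate 1.

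Fitted over all arrays as 2 added factors, a model chosen after the data were seen, inoculation called 5372 higher and 7961 lower probe sets and earthworms called 0 (limma), with 926 at an unadjusted p under 0.05. With a 2-fold limit added the balance for inoculation turned, to 2809 higher and 2510 lower.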

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

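The tests on control replicate 1 and on shared controls here were chosen after their results had been seen. A test of the difference itself passed for 3 probe sets without gene names, all near the floor in every group but control: for Ta.15208.1.S1_x_at, Ta.16315.2.A1_x_at and Ta.30790.3.S1_x_at the means were 2.02, 2.65 and 2.29 with Ggt and 2.29, 2.79 and 2.54 with earthworms. The falls with earthworms given below are therefore to the floor and not exact sizes. Little further fall with earthworms could be measured in inoculated plants, so each difference is close to the fall in uninoculated plants with the sign reversed and does not show a different action of earthworms with the fungus. For Ta.15208.1.S1_x_at the difference was 3.80 (limma adjusted p = 0.000103), with an earthworm change of −3.81 without Ggt and −0.01 with it. For Ta.30790.3.S1_x_at it was 2.53 (adjusted p = 0.0156; −2.48 and 0.05), and for Ta.16315.2.A1_x_at 2.00 (adjusted p = 0.0156; −2.01 and −0.01). Of these 3 calls, 1 was kept without control replicate 1.

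The separation of inoculated from uninoculated plants was weighed against technical explanations. Of 100 regroupings within earthworm treatment, 1, the real one, called as many probe sets (13333, highest other 62). That is the smallest share 100 regroupings can give, so chance is made unlikely but is not excluded. Quantile normalization kept 96.1% of the Ggt against control calls. The deposited arrays already had close quartiles (lower 2.37 to 2.43, upper 8.11 to 8.25), so it could move values little. It argues against leftover scaling differences in the deposited values and cannot speak to scaling before deposit. Control replicate 1 as the whole cause is argued against by the comparison with no control array in its group means. Of the probe sets called there and with Ggt against control, 1715 were higher in both, 3045 lower in both and 3 opposite. Shared calls were 5.27 times those of independent lists. That ratio is not an exact measure, since both comparisons take each probe set's spread from all arrays. A response to the fungus may account for the pattern. A batch that followed inoculation could also give it, and batches were not analysed here, so these cannot be told apart.

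Earthworm plants deviated from control, over all tested probe sets, in the direction of Ggt plants, although 2 of the 9 probe sets called higher with earthworms were called lower with Ggt. The covariance of the 2 sets of log2 changes was 0.325, against a mean of 0.113 in 100 simulated sets of unchanged groups, a difference of 0.211. Pearson's r was 0.536 against 0.548. The simulated noise was independent between probe sets, and noise common to many probe sets of a control array was not simulated. The difference of 0.211 therefore does not measure a shift beyond shared control noise. With 1 control array for each comparison the covariance was 0.290 or 0.106, between the bounds set for shared controls as the whole cause and for their exclusion. Without control replicate 1, 28.6% of the 28 earthworm calls were kept, which also decides nothing. With 2 control arrays, shared control noise and a real partial shift by earthworms cannot be told apart.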

How the results depend on the processing

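The averaged-factor counts, the later lists and the counts of called list members with an array left out were added after seeing the data. The 9730, 5611 and 9945 calls for the fungus kept more calls lower than higher under both rescalings, and no scaling moved the median of all probe sets by over 0.1. The causes of the shifts below were not tested, except that fewer arrays or probe sets enter some fits. With no filter earthworms against control gave 85, both against Ggt 2 and the interaction 33; with the strict filter each gave 0. The interaction gave 5 after quantile normalization, 7 with the trended prior and 10 with array weights. Earthworms against control gave 8 with the pseudocount of 16 and 15 with array weights, which gave 8621 for both against earthworms. With only the groups compared, Ggt against control gave 4385, earthworms against control 0 and both against Ggt 0. The replicate block gave 1, 0, 3513 and 1 for earthworms against control, both against Ggt, both against earthworms and the interaction, and 5333 for the F test; of 13 same-numbered pairs 2 correlated above 0.1 (−0.48 to 0.37) and 2 of 10 arrays correlated best with their own number. At unadjusted p under 0.01 and 2-fold the counts were 5284, 346, 11, 3107, 5278 and 188 in the order Ggt against control, earthworms against control, both against Ggt, both against earthworms, both against control, interaction, then 5004 (2572 higher and 2432 lower, a turned balance) and 6 for the averaged fungus and earthworm effects and 5077 for the F test. At adjusted p under 0.05 and 2-fold they were 5613 for Ggt, 3021 and 5651 for both against earthworms and against control, 5319 averaged (2809 higher and 2510 lower) and 5396 for the F test. Called lists went from 4 to 1 with an estimated correlation and to 1 with 1 probe set per gene for the fixed list, and from 12 to 1 and 5 (1 probe set per gene) for the later lists. With fry 0 of these 12 were kept, and the 3 later-list calls it gave were all of the fructan and starch list, which camera did not call. Fry called the fixed redox list lower in Ggt against control, both against earthworms and both against control (fry adjusted p = 0.000353, 0.00216 and 0.00169). It did not call that list in both against Ggt (0.134). The 5 kept with 1 probe set per gene were defence and photosynthesis for both against Ggt, photosynthesis and tubulin for both against control, and tubulin for both against earthworms. Leaving out 1 array, where a lone control or earthworm array is assumed to vary like the other groups, gave 4711 to 10622 for Ggt against control, 6 to 1784 for earthworms against control, 0 to 4 for both against Ggt, 1724 to 6651 for both against earthworms, 4651 to 11049 for both against control, 1 to 762 for the interaction, 11337 to 13529 for the averaged fungus effect, 5559 to 9719 for the F test, 3 to 5 fixed-list and 10 to 14 later-list calls; the averaged earthworm effect stayed at 0. Of 1160 gene results with an array left out 954 kept their call, 206 lost it and 0 reversed. With all arrays, of 116 gene results 24 lost their call without the filter and 20 with the replicate block. With only the groups compared 32 of 116 lost it. Dim transcripts near the floor of the arrays limit how well falls can be sized.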

Other observations

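Lists not yet described gave the following in Ggt against control. Of 5 fructan and starch probe sets 2 fell, both of 6-FEH (−2.11 and −2.40, the latter with adjusted p = 0.0903 without control replicate 1), and beta-amylase BMY1 at 1.20 did not pass. Fry called this list lower in Ggt against control (adjusted p = 0.0035), both against earthworms (0.0403) and both against control (0.00393), where camera did not (0.307, 0.367 and 0.468). Of 9 translation probe sets RPL9 and 1 of 2 RPS29 probe sets rose, and eIF4E and NCBP fell; the other RPS29 probe set was at −0.51 and did not pass. Without control replicate 1 the RPS29 rise and the NCBP fall no longer passed (adjusted p = 0.0529 and 0.134). Of 8 glutathione-related probe sets 2 rose and 3 fell, 1 of the falls being kept when either control array is left out. Of 3 tested grain-tissue probe sets of 27 on the array 1 fell, the avenin-like avnlb (−0.84).

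The dehydration test was chosen after its result had been seen, and the regroupings were planned beforehand. The hypothesis that uninoculated leaves at 52 days held a dehydration response predicts that several genes of the dehydration list are high there. Of 5 genes on the list 2 lay above the filter, and 2 of them, Rab15 and LEA1, were lower in both comparisons of inoculated with uninoculated plants. A first count took adjusted p values from the fit without the filter and held Rab15 alone, since LEA1 had adjusted p = 0.0719 there for both treatments against earthworms; the count of 2 uses the filtered fit and was chosen after the first had been seen. The Em and COR410 probe sets lay at group means of 3.13 or less in every group, so these genes did not measure as high in uninoculated leaves. The test asked for more measured genes than these 2, so it could not decide and the hypothesis stays undecided.

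For both treatments against Ggt, 3 of the 10 splits of the 6 inoculated arrays called as many probe sets as the real 1 (highest other 11), and 10 splits are too few for a share under 0.05. For earthworms averaged over inoculation, 60 of 60 regroupings within inoculation called at least the real 0 (highest other 148), which any count does, so this says nothing about chance.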
